A study of Mus musculus with 18 samples.

How the data were processed

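Total RNA of sorted mouse hematopoietic cells was measured on Affymetrix Clariom S arrays, 1 array per sample and 18 arrays in all. Per the labels' protocols, RNA was extracted with an RNeasy Micro kit and biotin-labelled cRNA was made from 2 ng of total RNA with the GeneChip Pico kit and 10 cycles of PCR before in vitro transcription. The deposited values are log2 signals, 1 per probe set and array, which the authors made in R 3.5.01 with the oligo package, per the submitters' processing notes. The background correction, the normalization between arrays, the summarization and any filter are not given in the sources used here. The largest difference between arrays at the same rank was 0.34 on the log2 scale, with a median over ranks of 0.25, so the listed values are close to but not exactly quantile normalized.

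Arrays were grouped by the titles, source names and cell type labels into 6 groups of 3, fetal liver (FL) or bone marrow (BM) by long-term hematopoietic stem cells (LT-HSC), short-term hematopoietic stem cells (ST-HSC) or multipotent progenitors (MPP), with the replicate letters a, b and c of the titles. Of the 22203 probe sets listed, 19572 carried 1 gene symbol in the platform annotation, and each of these matched a gene of the RefSeq table of GRCm38.p6, which was used for names only. The other 2631 probe sets carried no symbol or several and were left out of the gene tests. For symbols with more than 1 probe set the one with the highest mean over the 18 arrays was used, which set aside 67 probe sets and left 19505 genes.

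The means of the 6 groups were fitted to the log2 values of all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that all groups shared 1 estimate of the spread per gene. From this fit came 10 comparisons between groups, the interaction contrast of LT-HSC against MPP between FL and BM, and a moderated F test of the whole interaction of source and population. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested are named as called, higher or lower. Errors of log2 differences are the standard errors of this fit, and errors of means are SD. The number of arrays limits the precision: the median standard error was 0.17 on the log2 scale for a comparison of 3 arrays with 3, 0.10 for the average over populations and 0.24 for the interaction contrast. On simulated data with 200 changed genes and 20 draws, changes of log2 1 were recovered at 98.2% for the average of FL against BM, 79.6% for FL against BM in LT-HSC, 81.6% for LT-HSC against MPP in FL and 47.8% for the interaction contrast. For changes of log2 2 the shares were 100%, 99.4%, 99.3% and 93.8%, in the same order, and 5.09%, 5.15%, 4.39% and 4.61% of the calls were false. Each gene and array was drawn independently, so the simulated data hold no structure shared between arrays. These shares, the false calls among them, may therefore not carry over to the measured data.

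Before the data were examined, the groups, the tests, the alternatives other than the last 3 listed, 34 gene lists and the rule for named genes were fixed. Of the lists, 31 were tested as sets in each contrast with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation. Over the 11 contrasts camera made 206 list calls with the preset correlation, of which 39 held with an estimated one. The other lists, sex-linked genes, sort markers and Ezh2, only checked the labels. Members were counted after adjustment over all genes and, as stated, adjusted over the list alone. On simulated data, with each gene drawn independently, a shift of 0.3 in the S phase list was called in 100% of the draws. In the measured data the estimated correlation within this list was 0.30, so that share does not carry over to it. Genes named are, per contrast, the 10 with the largest positive and the 10 with the largest negative difference among called genes whose 3 arrays of one group all lay above the 3 of the other (for the average over populations, within each of the 3 populations), up to 4 members of each list with the largest absolute difference, list members needed to explain a count of 5 or fewer, and all members of the check lists.

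Alternatives changed 1 choice at a time: leaving out each array, median centring, repeated quantile normalization, leaving out the dimmest 30% of genes, the mean of a gene's probe sets, all probe sets, array weights, eBayes with a trend and robust estimation, a fit of only the groups compared, a fold of at least 2 beside the adjusted p, leaving out the arrays described as sgEzh2, leaving out FL ST-HSC b and c, a replicate block, and lists without members shared between lists. The replicate block was fixed or a random effect, and for the average the mean over populations per source and letter was also tried. Leaving out 4 arrays with a narrow spread, a covariate for the spread of each array and a covariate for the mean of the hepatocyte list were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.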

Results

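Hematopoietic stem and progenitor cells of C57Bl/6J mice were compared between the fetal liver (FL), their main site of expansion before birth, and the adult bone marrow (BM). FL cells came from E13.5 embryos and BM cells from adults aged 3 to 12 months. From each source LT-HSC, ST-HSC and MPP were sorted as lineage-negative cells positive for Sca-1 and Kit (LSK), divided by Cd150 and Cd48; the exact gates are not given in the sources used here. Each of the 6 groups held 3 arrays, lettered a, b and c. Array medians lay between 7.68 and 7.78 on the log2 scale, and arrays of a group correlated at 0.961 to 0.995 over genes, against 0.936 to 0.988 for arrays of different groups. The interquartile range was 2.98 to 3.18 in 14 arrays but 2.71 in FL LT-HSC b, 2.63 in BM ST-HSC b, 2.65 in BM ST-HSC c and 2.61 in BM LT-HSC c, which are named as the 4 narrow arrays. Nothing in the labels says that the arrays of a group came from separate animals, so p-values measure only the spread between these samples. The free-text descriptions of the arrays speak of transplanted marrow and name sgEzh2 for 4 FL arrays and sgLuc for the rest, against the titles, source names and stages, and the latter were used.

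**Figure D1:**
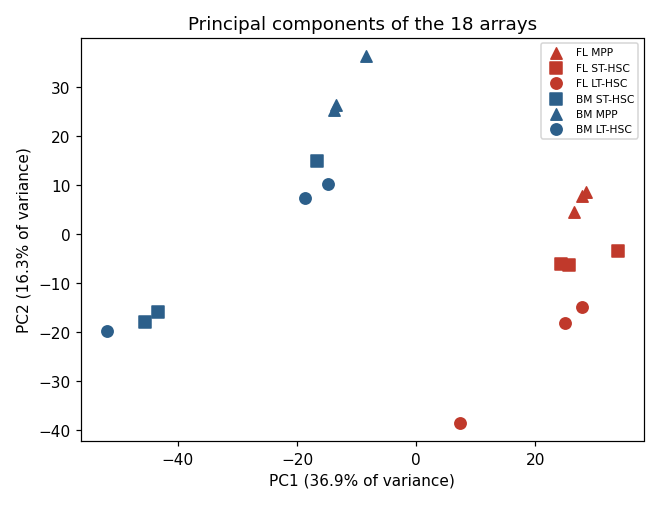
Principal components of the 18 arrays over the genes tested, with component 1 (36.9% of the variance) on the horizontal and component 2 (16.3%) on the vertical axis, FL in red and BM in blue, circles for LT-HSC, squares for ST-HSC and triangles for MPP. All FL arrays have positive and all BM arrays negative values of component 1, and the 4 narrow arrays lie lowest or among the lowest on component 2.

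The sort markers were examined first. Kit, the receptor of the LSK gate, was at 13.19 ± 0.11 in FL and 13.15 ± 0.15 in BM (mean log2 value ± SD, n = 9 arrays each). Slamf1, which encodes Cd150, was at 9.31 ± 0.18 in FL LT-HSC, 7.49 ± 0.10 in FL ST-HSC and 6.71 ± 0.24 in FL MPP, and at 9.66 ± 0.40, 8.04 ± 0.22 and 7.25 ± 0.14 in the same populations of BM (n = 3 each). Cd48 was at 12.35 ± 0.003 in FL MPP and 12.26 ± 0.08 in BM MPP, and lower in LT-HSC and ST-HSC of FL (9.79 ± 0.21 and 9.96 ± 0.06) and BM (10.32 ± 0.95 and 9.83 ± 0.38). The wide spread of BM LT-HSC came from array c, with Cd48 at 11.40. In this array the mean of 8 neutrophil genes, most of them for granule proteins and named granule genes below, was 12.92. It was 10.37 to 11.68 in the other BM arrays. Flt3, a receptor of multipotent and lymphoid-primed progenitors, rose from LT-HSC (7.48 ± 0.03 in FL and 7.19 ± 0.23 in BM) to MPP (9.46 ± 0.08 and 10.10 ± 0.05). Of the Y-linked genes, Kdm5d was at 7.50 ± 0.46 in FL and 4.55 ± 0.24 in BM, and Uty at 7.28 ± 0.30 and 3.92 ± 0.12 (n = 9 each), while Eif2s3y, at 5.15 ± 0.28 and 4.91 ± 0.23, did not pass. Ezh2, named in the free-text descriptions, was at 10.65 ± 0.07 in the 4 FL arrays described as sgEzh2 and 10.72 ± 0.11 in the other 5, a difference of -0.07 (two-sided exact permutation p = 0.317). The sgEzh2 arrays were FL MPP a and b, FL ST-HSC a and FL LT-HSC a, and the permutation ignored population. This check therefore does not settle which labels are right.

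To ask how fetal and adult cells differ whatever the population, FL was compared with BM over LT-HSC, ST-HSC and MPP weighted equally, with 9 arrays on each side. FL cells had higher levels of genes known from fetal tissues: Mir675, the microRNA gene within H19, by 4.37 ± 0.09 (log2 difference ± SE, 20.7-fold), the imprinted growth factor Igf2 by 2.48 ± 0.09, the imprinted Notch-family ligand Dlk1 by 3.02 ± 0.09, and the RNA-binding proteins Igf2bp3 and Lin28b, the latter a block to let-7 maturation, by 2.55 ± 0.10 and 1.93 ± 0.15. The actin-bundling protein Fscn1 (3.51 ± 0.18), Spats2 (3.41 ± 0.11) and the cadherin Cdh17 (2.94 ± 0.11) were also higher. BM cells had higher levels of neutrophil genes, with Lcn2 at -5.95 ± 0.27, Ngp at -5.77 ± 0.21 and S100a8 at -4.95 ± 0.30, and of Dntt, the DNA polymerase that adds nucleotides to antigen receptor joints (-3.89 ± 0.21). The immediate early transcription factor gene Fos (-3.27 ± 0.15) and H2-Eb1, a chain of MHC class II (-2.73 ± 0.14), were lower in FL too. Adjusted p was between 1.35e-15 and 3.17e-08 for these genes. Here and below, a named gene passed at an adjusted p under 0.05 unless it is said not to have passed. For the genes so named, every array of the higher group lay above every array of the lower within each population or source. The rule for named genes required this of those with the largest differences. The exceptions, all in the average, were Mmrn1 in LT-HSC, Pdzk1ip1 in LT-HSC and ST-HSC and Afp in ST-HSC, where the arrays of FL and BM overlapped. Of all 4904 genes called in the average, 1434 were separated in this way in each population.

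Medians of lists are over the log2 differences of all members measured. Among the lists higher in FL, 7 of 11 fetal oncofetal genes were higher and 4 did not pass, 7 passed adjusted over the list alone. The median was 0.90 (camera adjusted p = 5.85e-07). Beside Igf2bp3 and Lin28b it held Mycn (1.32 ± 0.14) and Arid3a (0.98 ± 0.08). Of the parentally imprinted genes, 10 of 21 imprinted genes were higher, 2 were lower and 9 did not pass, 10 and 2 passed adjusted over the list alone. The median was 0.57 (camera adjusted p = 0.000136, adjusted p = 0.056 with an estimated correlation). Ndn rose with Igf2 and Dlk1 (1.51 ± 0.12). Genes of DNA replication were higher, as 35 of 47 S phase genes were higher and 12 did not pass, 39 passed adjusted over the list alone. The median was 0.38 (camera adjusted p = 6.45e-15, adjusted p = 0.0817 with an estimated correlation). Nasp, a histone chaperone, differed by 1.12 ± 0.11 and the exonuclease gene Exo1 by 1.01 ± 0.13. For mitosis, 38 of 53 G2M phase genes were higher within ST-HSC, against 1 within LT-HSC and 1 within MPP, where 1 was lower. In the average 33 were higher, 1 was lower and 19 did not pass, 39 and 1 passed adjusted over the list alone. The median was 0.41 (camera adjusted p = 8.7e-11, adjusted p = 0.217 with an estimated correlation); the spindle checkpoint genes Bub1b (1.06 ± 0.17) and Bub1 (1.01 ± 0.17) led. Without the 4 narrow arrays 31 S phase genes and 28 G2M phase genes were higher.

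Members of several groups were lower in FL. For myeloid priming, 1 of 32 myeloid-priming genes was higher, 24 were lower and 7 did not pass, 1 and 25 passed adjusted over the list alone. The median was -1.16 (camera adjusted p = 5.16e-22, adjusted p = 0.0604 with an estimated correlation). The neutrophil genes Camp (-4.79 ± 0.20) and S100a9 (-4.40 ± 0.24) were lower, and so was Ly6c2 (-4.67 ± 0.20). Ly6c2 shares much sequence with its paralog Ly6c1, so the signal of each is uncertain. Late neutrophil markers, 12 genes written down before they were tested, had a median difference of -1.22, with 10 of them lower. In antigen presentation, 18 of 24 antigen presentation genes were lower and 6 did not pass, 18 passed adjusted over the list alone. The median was -1.14 (camera adjusted p = 2.71e-23), with H2-Ab1 at -2.29 ± 0.15 and H2-DMa at -1.81 ± 0.09; probes of H2 genes can share sequence with other members of the family. Among targets of interferon, 28 of 42 interferon response genes were lower and 14 did not pass, 29 passed adjusted over the list alone. The median was -0.43 (camera adjusted p = 1.47e-15), and Iigp1, an immunity-related GTPase, and Ifi27 fell by 1.54 and 1.39. In the immediate early response, 26 of 30 immediate early genes were lower and 4 did not pass, 26 passed adjusted over the list alone. The median was -1.07 (camera adjusted p = 4.99e-26), and Fosb (-3.39 ± 0.23), Nr4a1 (-2.90 ± 0.21) and Egr1 (-2.74 ± 0.22) were lower with Fos. For cell cycle restraint, 2 of 22 cell cycle inhibitors and quiescence genes were higher, 11 were lower and 9 did not pass, 3 and 11 passed adjusted over the list alone. The median was -0.31 (camera adjusted p = 3.03e-07), with Nr4a2 (-2.56 ± 0.21) and the antiproliferative gene Btg2 (-1.79 ± 0.13) among those that fell. Egr1, Nr4a1 and Btg2 are members of both this list and the immediate early list, so the results of these lists are not independent.

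Markers of other blood lineages were among the genes lower in FL. Among B cell markers, 14 of 17 B cell genes were lower and 3 did not pass, 14 passed adjusted over the list alone. The median was -1.09 (camera adjusted p = 2.07e-13, adjusted p = 0.0644 with an estimated correlation), with Jchain, the joining chain of antibodies, at -3.59 ± 0.25 and Vpreb3, a pre-B cell protein, at -1.98 ± 0.21. For platelets, 1 of 27 megakaryocyte and platelet genes was higher, 10 were lower and 16 did not pass, 1 and 11 passed adjusted over the list alone. The median was -0.25 (camera adjusted p = 2.13e-07). Thrombospondin Thbs1 (-1.87 ± 0.12) and the platelet chemokine Pf4 (-1.47 ± 0.09) fell, while the adhesive protein Mmrn1 was the member that rose (1.13 ± 0.12). Among macrophage markers, 12 of 22 macrophage genes were lower and 10 did not pass, 14 passed adjusted over the list alone. The median was -0.50 (camera adjusted p = 2.8e-08, adjusted p = 0.159 with an estimated correlation), with C1qa at -1.88 ± 0.15 and Cd163 at -1.51 ± 0.15. For granulocytes of allergy, 2 of 18 mast cell, basophil and eosinophil genes were higher, 7 were lower and 9 did not pass, 2 and 9 passed adjusted over the list alone. The median was -0.32 (camera adjusted p = 0.000826, adjusted p = 0.214 with an estimated correlation), with the basophil protease Mcpt8 at -3.07 ± 0.23. In the T and NK group, 1 of 19 T and NK cell genes was higher, 7 were lower and 11 did not pass, 1 and 8 passed adjusted over the list alone. The median was -0.28 (camera adjusted p = 0.00126, adjusted p = 0.356 with an estimated correlation), and Nkg7 differed by -1.66 ± 0.13. Of the stromal markers, 1 of 21 stromal and stellate cell genes was higher, 8 were lower and 12 did not pass, 1 and 9 passed adjusted over the list alone. The median was -0.24 (camera adjusted p = 3.61e-05, adjusted p = 0.148 with an estimated correlation); the member that rose was Postn (2.29 ± 0.13), and Gas6 (-1.54 ± 0.11) fell.

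Other groups were mixed. Of LT-HSC-associated genes 9 were higher and 11 lower among 38, 11 and 11 adjusted over the list alone, with Fgd5 at 1.64 ± 0.12 and Pdzk1ip1 at -1.17 ± 0.16; the median (-0.07) and the test pointed down and the mean (0.03) up (camera adjusted p = 0.39). Lymphoid-priming genes split into 5 higher and 5 lower of 20, 8 and 6 adjusted over the list alone, with Cnn3 at 2.14 ± 0.14 against Dntt; the median was 0.14 and the mean -0.02 (camera adjusted p = 0.775, upward). Erythroid genes were 2 higher and 4 lower of 27, also adjusted over the list alone, with the embryonic globin Hbb-y at 2.20 ± 0.44 and the carbonic anhydrase Car1 at -3.60 ± 0.27, a median of 0.07 and a mean of -0.08 (camera adjusted p = 0.426, downward). In the vessel wall group, 7 of 19 endothelial genes were higher, 1 was lower and 11 did not pass, 8 and 1 passed adjusted over the list alone. The median was 0.17 (camera adjusted p = 0.000524, adjusted p = 0.0899 with an estimated correlation), led by the endothelial cadherin Cdh5 (1.51 ± 0.12) and Ptprb (1.38 ± 0.14). Of liver cell markers, 7 of 24 hepatocyte and hepatoblast genes were higher, 2 were lower and 15 did not pass, 9 and 2 passed adjusted over the list alone. The median was 0.18 (camera adjusted p = 0.0357, adjusted p = 0.545 with an estimated correlation). Albumin (Alb, 2.71 ± 0.40) and alpha-fetoprotein (Afp, 1.53 ± 0.36) led, and Alb ran from 7.77 to 11.79 over the FL arrays, highest in FL LT-HSC c, against 6.50 to 7.17 in BM. The hepatocyte call was lost without FL ST-HSC b (adjusted p = 0.0791), FL LT-HSC c (0.0697), BM ST-HSC a (0.0771), BM MPP b (0.0605), BM LT-HSC a (0.0621) or BM LT-HSC b (0.0692).

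In all, 4904 of 19505 genes were called by limma in this average, 3098 higher and 1806 lower in FL. The balance turned among the 443 that differed at least 2-fold, 136 higher and 307 lower, and was 2285 to 1999 of 4284 without the 4 narrow arrays. With the hepatocyte list mean as a covariate 2786 were called, and without the 4 FL arrays described as sgEzh2, which leaves 1 FL MPP array, 2538. The array values of Igf2bp3, Lin28b, Igf2, Lcn2, H2-Eb1 and Fos show the separation of FL from BM in each population.

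**Figure D2:**
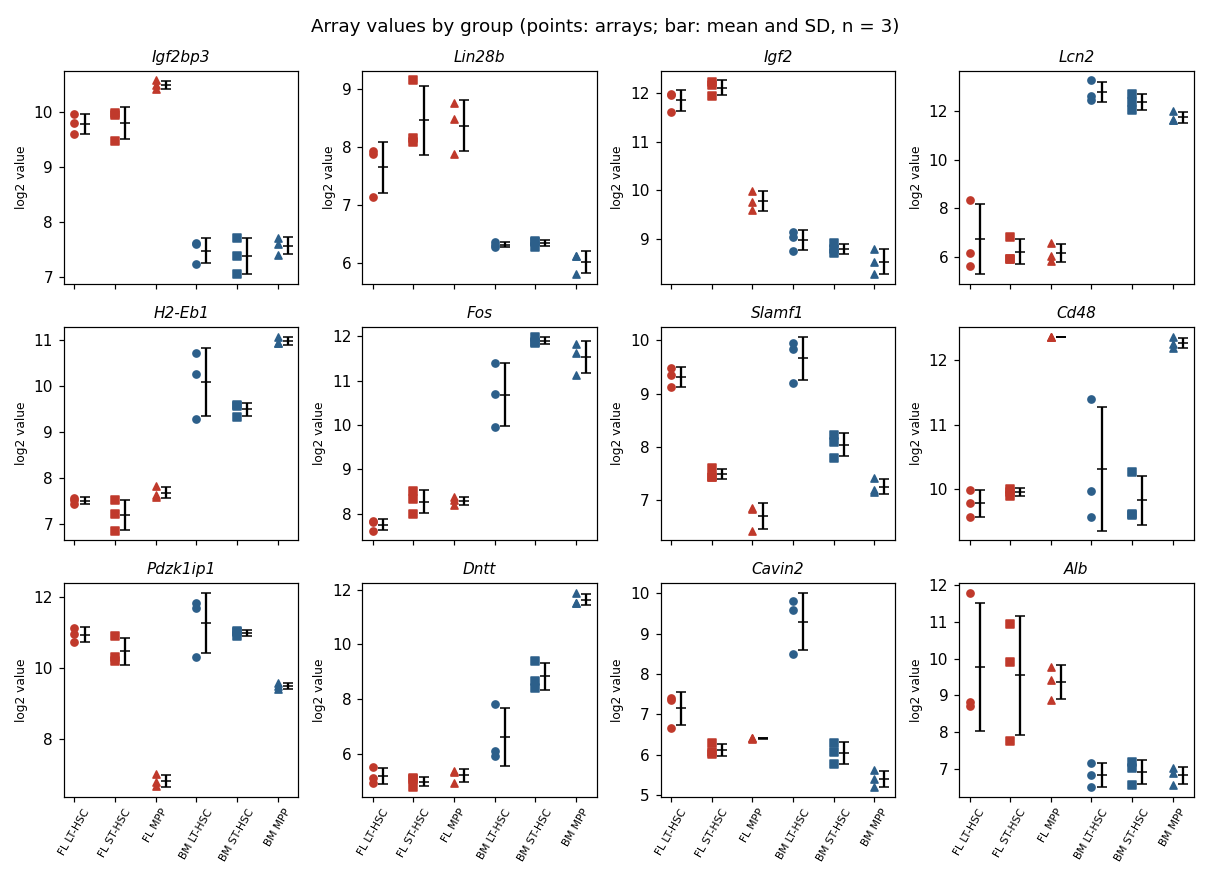
Log2 values of 12 genes (vertical axes) in the 6 groups (horizontal axes), with points for arrays and bars for the mean and SD of 3 arrays. Igf2bp3, Lin28b and Igf2 are higher and Lcn2, H2-Eb1 and Fos lower in every FL group than in the BM group of the same population, while Alb is spread most between the arrays of FL LT-HSC and FL ST-HSC.

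FL was then compared with BM within each population, 3 arrays against 3. In LT-HSC, the population of longest engraftment, Mir675 (4.47 ± 0.16), Igf2 (2.87 ± 0.16), Dlk1 (2.81 ± 0.16), Nrep (2.58 ± 0.15) and Igf2bp3 (2.30 ± 0.18) were higher in FL. S100a8 (-6.37 ± 0.53), Lcn2 (-6.07 ± 0.47), the neutrophil collagenase Mmp8 (-5.92 ± 0.38) and Ngp (-5.77 ± 0.37) were lower. The eosinophil granule protein Prg2 (-3.69 ± 0.63) and the complement gene C1qa (-3.14 ± 0.26) were lower as well, and Cd34 was higher by 1.13 ± 0.13. For platelet genes, 12 of 27 megakaryocyte and platelet genes were lower and 15 did not pass, 13 passed adjusted over the list alone. The median was -0.35 (camera adjusted p = 1.06e-11), with Pf4 at -2.41 ± 0.16 and Cavin2 at -2.15 ± 0.26. Of the B cell markers, 11 of 17 B cell genes were lower and 6 did not pass, 15 passed adjusted over the list alone. The median was -1.71 (camera adjusted p = 1.13e-20), with Vpreb3 (-2.96 ± 0.36) and the B cell factor Ebf1 (-2.39 ± 0.21) among those lower. For the myeloid group, 24 of 32 myeloid-priming genes were lower and 8 did not pass, 25 passed adjusted over the list alone. The median was -2.12 (camera adjusted p = 1.34e-37); the late neutrophil markers had a median of -2.09, with 9 of 12 lower. For stromal markers, 1 of 21 stromal and stellate cell genes was higher, 8 were lower and 12 did not pass, 1 and 11 passed adjusted over the list alone. The median was -0.45 (camera adjusted p = 3.82e-09), with Sparc at -2.91 ± 0.45. Without the 4 narrow arrays, among them BM LT-HSC c with the highest late neutrophil mean, the medians were -1.27 for B cell genes, -1.68 for myeloid-priming genes and -0.24 for stromal and stellate cell genes. Among the fetal genes, 5 of 11 fetal oncofetal genes were higher and 6 did not pass, 7 passed adjusted over the list alone. The median was 0.58 (camera adjusted p = 2.25e-05), with Hmga2 at 0.93 ± 0.19, and 7 of 21 imprinted genes were higher, 1 was lower and 13 did not pass, 9 and 1 passed adjusted over the list alone. The median was 0.57 (camera adjusted p = 6.77e-06), with Peg3 at 1.52 ± 0.17 and Plagl1 at 1.51 ± 0.23. In the S phase list, 11 of 47 S phase genes were higher and 36 did not pass, 23 passed adjusted over the list alone. The median was 0.34 (camera adjusted p = 9.41e-11, adjusted p = 0.124 with an estimated correlation), while 1 G2M phase gene was higher, also adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.000291, adjusted p = 0.505 with an estimated correlation); without the 4 narrow arrays 9 were. Fos (-2.93 ± 0.25) and H2-Eb1 (-2.58 ± 0.25) fell as in the average. Tek, an angiopoietin receptor, did not pass (1.17 ± 0.36, adjusted p = 0.0557). Of 1495 genes called, 601 were higher and 894 lower, and 947 were called without FL LT-HSC a. A fit of FL and BM LT-HSC alone called 372, and 854 were called with the hepatocyte covariate, 684 without the sgEzh2 arrays and 2645 (1337 higher and 1308 lower) with the array spread as a covariate.

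In ST-HSC, Mir675 (4.84 ± 0.16), Cdh17 (3.87 ± 0.19), Rasgrp3 (3.35 ± 0.25), Igf2 (3.31 ± 0.16) and Ccr9 (2.91 ± 0.37) were higher in FL, and Lcn2 (-6.18 ± 0.47), Ngp (-6.04 ± 0.37), Car1 (-4.17 ± 0.47), Dntt (-3.84 ± 0.36) and Nr4a1 (-3.78 ± 0.37) lower. The lymphoid cytokine receptor Il7r was higher by 1.38 ± 0.29. Cell cycle genes were higher in FL: 33 of 47 S phase genes were higher and 14 did not pass, 41 passed adjusted over the list alone. The median was 0.64 (camera adjusted p = 2.1e-17, adjusted p = 0.0761 with an estimated correlation), and 38 of 53 G2M phase genes were higher and 15 did not pass, 43 passed adjusted over the list alone. The median was 0.78 (camera adjusted p = 1.75e-17, adjusted p = 0.177 with an estimated correlation). Bub1b differed by 2.01 ± 0.29 and Bub1 by 1.96 ± 0.29. BM ST-HSC b and c are narrow arrays, and without the 4 narrow arrays, which leaves 1 BM ST-HSC array, 10 S phase and 5 G2M phase genes were higher and Ttk, a checkpoint kinase at 1.62 ± 0.28, was not called (0.76, adjusted p = 0.124). In the endothelial list, 9 of 19 endothelial genes were higher and 10 did not pass, 10 passed adjusted over the list alone. The median was 0.41 (camera adjusted p = 4.31e-05, adjusted p = 0.0761 with an estimated correlation), with Cdh5 at 2.79 ± 0.21. For antigen presentation, 17 of 24 antigen presentation genes were lower and 7 did not pass, 17 passed adjusted over the list alone. The median was -1.06 (camera adjusted p = 9.61e-15), and for immediate early genes, 24 of 30 immediate early genes were lower and 6 did not pass, 26 passed adjusted over the list alone. The median was -1.20 (camera adjusted p = 1.06e-20), with Fos at -3.63 ± 0.25. Of 3638 genes called, 2367 were higher and 1271 lower in FL. Without the narrow arrays 1207 were called, 43.0% of them higher against 65.1%, and leaving out 1 array gave 1725 (FL ST-HSC b), 6125 (BM ST-HSC a), 1587 (BM ST-HSC b) and 1462 (BM ST-HSC c). Array weights gave 8827, the array spread as a covariate 1755, 885 higher and 870 lower, and leaving out the sgEzh2 arrays 1462.

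In MPP, Fscn1 (4.95 ± 0.31), Cdh17 (4.28 ± 0.19), Spats2 (3.91 ± 0.20), Dlk1 (3.19 ± 0.16), Igf2bp3 (2.93 ± 0.18) and Lin28b (2.35 ± 0.26) were higher in FL. Dntt (-6.42 ± 0.36), Lcn2 (-5.60 ± 0.47), Ngp (-5.49 ± 0.37) and Jchain (-5.28 ± 0.44) were lower, Dntt at 5.22 ± 0.24 against 11.63 ± 0.21 (mean ± SD, n = 3 each). Igf2 differed by 1.25 ± 0.16, and Mmrn1 (2.30 ± 0.21) was higher while Selp, a platelet and endothelial selectin, was lower (-1.67 ± 0.15). Of the fetal genes, 6 of 11 fetal oncofetal genes were higher and 5 did not pass, 7 passed adjusted over the list alone. The median was 0.73 (camera adjusted p = 1.81e-10), with Mycn at 1.60 ± 0.24. Among B cell markers, 8 of 17 B cell genes were lower and 9 did not pass, 10 passed adjusted over the list alone. The median was -0.87 (camera adjusted p = 1.82e-13, adjusted p = 0.0858 with an estimated correlation), with the surrogate light chain Vpreb1 at -2.14 ± 0.29 and the adaptor Blnk at -1.94 ± 0.28. H2-Eb1 (-3.30 ± 0.25) and H2-Ab1 (-2.66 ± 0.26), chains of MHC class II, were lower, and 16 of 24 antigen presentation genes were lower and 8 did not pass, 18 passed adjusted over the list alone. The median was -1.12 (camera adjusted p = 2.53e-33). For interferon, 15 of 42 interferon response genes were lower and 27 did not pass, 25 passed adjusted over the list alone. The median was -0.45 (camera adjusted p = 5.52e-21), with Iigp1 at -1.73 ± 0.22 and Gbp3, a guanylate-binding protein, at -1.42 ± 0.21. In the immediate early group, 21 of 30 immediate early genes were lower and 9 did not pass, 24 passed adjusted over the list alone. The median was -1.03 (camera adjusted p = 2.53e-33). Of the myeloid genes, 15 of 32 myeloid-priming genes were lower and 17 did not pass, 20 passed adjusted over the list alone. The median was -0.93 (camera adjusted p = 2.14e-20, adjusted p = 0.0858 with an estimated correlation), led by Ly6c2 (-4.82 ± 0.34), while the late neutrophil markers had a median of -0.20 with 4 of 12 lower. For mitosis, 1 of 53 G2M phase genes was higher, 1 was lower and 51 did not pass, and none passed adjusted over the list alone. Their median was 0.19 (camera adjusted p = 0.0333, adjusted p = 0.65 with an estimated correlation). For replication, 3 of 47 S phase genes were higher and 44 did not pass, 3 passed adjusted over the list alone. The median was 0.21 (camera adjusted p = 0.000326, adjusted p = 0.446 with an estimated correlation); without the narrow arrays 9 were higher. In all 1067 genes were called, 375 higher and 692 lower, and 2136 without the narrow arrays, 960 higher and 1176 lower. More were higher than lower with array weights (1958 and 1648) and in a fit of FL and BM MPP alone (1413 and 1347), 1001 and 1028 were with the array spread as a covariate, and 261 were called without the sgEzh2 arrays, which leaves 1 FL MPP array. Leaving out 1 array gave 698 (FL MPP a), 701 (FL MPP b), 671 (FL MPP c), 635 (BM MPP b) and 693 (BM MPP c).

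**Figure D3:**
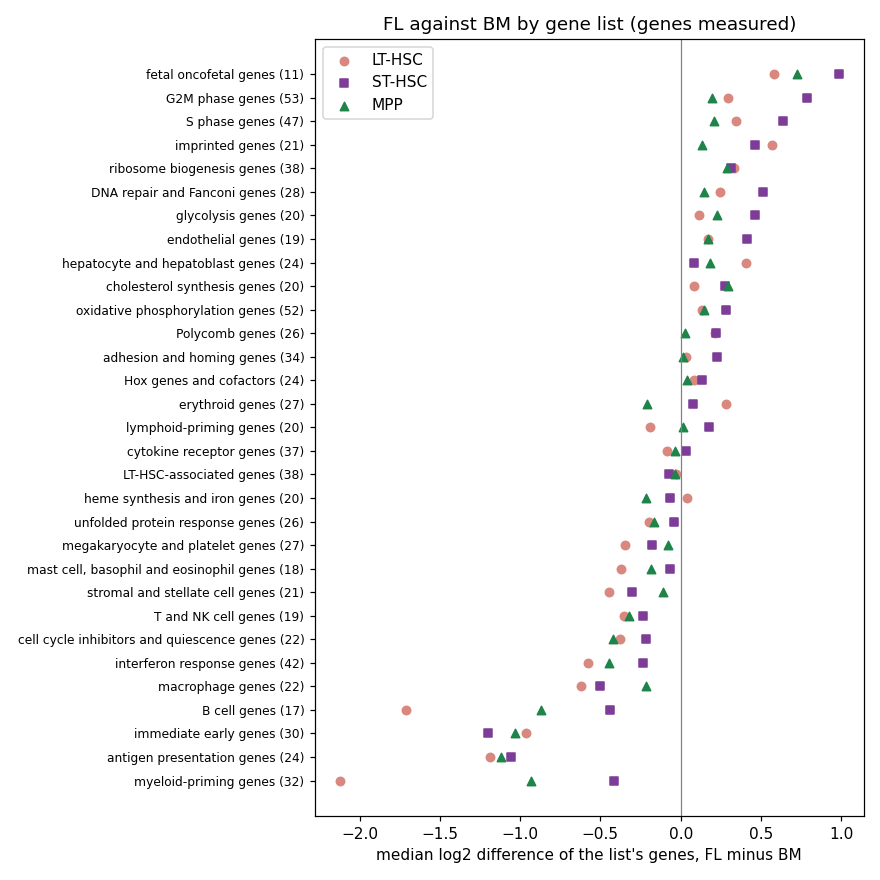
Median log2 difference of FL minus BM (horizontal axis) over the measured genes of each of the 31 lists (vertical axis, with the number of genes), for LT-HSC (circles), ST-HSC (squares) and MPP (triangles). The myeloid, B cell, antigen presentation and immediate early lists lie left of 0 and the fetal oncofetal, imprinted, S phase and G2M phase lists right of 0 in all 3 populations.

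Calls were shared between populations: 173 genes were higher and 286 lower in FL in all 3, of 4500 called in at least 1. LT-HSC and ST-HSC shared 461 higher and 426 lower genes, where independent lists of those lengths would share 72.9 and 58.3, and 12 genes moved in opposite directions. LT-HSC and MPP shared 181 and 368 (11.6 and 31.7 if independent, 7 opposite), and ST-HSC and MPP 300 and 403 (45.5 and 45.1 if independent, 5 opposite).

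LT-HSC were compared with MPP within each source to ask how the most primitive cells differ from their multipotent progeny. In FL, Pdzk1ip1, a membrane protein of stem cells, was higher in LT-HSC by 4.12 ± 0.28, Slamf1 by 2.60 ± 0.18, the transcription factor Mecom by 2.29 ± 0.26, the fibronectin gene Fn1 by 2.63 ± 0.33 and Tek by 2.28 ± 0.36. Cdh17 (-3.77 ± 0.19), Ccr9 (-3.60 ± 0.37), the RNA sensor Tlr7 (-3.71 ± 0.35), the neutrophil protease Ctsg (-3.61 ± 0.41), Il7r (-2.69 ± 0.29) and Cd48 (-2.57 ± 0.30) were lower. Of the stem cell genes, 19 of 38 LT-HSC-associated genes were higher and 19 did not pass, 28 passed adjusted over the list alone. The median was 0.86 (camera adjusted p = 4.1e-27). For imprinted genes, 6 of 21 imprinted genes were higher and 15 did not pass, 11 passed adjusted over the list alone. The median was 0.61 (camera adjusted p = 2.2e-09), with Igf2 at 2.07 ± 0.16, Grb10, an adaptor of growth factor receptors, at 1.89 ± 0.28 and Plagl1 at 1.68 ± 0.23. In the platelet list, 11 of 27 megakaryocyte and platelet genes were higher, 1 was lower and 15 did not pass, 19 and 1 passed adjusted over the list alone. The median was 0.54 (camera adjusted p = 1.53e-16), with Selp at 1.60 ± 0.15, Rab27b at 1.59 ± 0.17 and Pf4 at 1.41 ± 0.16. Of the endothelial genes, 5 of 19 endothelial genes were higher and 14 did not pass, 7 passed adjusted over the list alone. The median was 0.36 (camera adjusted p = 1.73e-08), with Cdh5 at 2.47 ± 0.21 and the VEGF receptor Kdr at 1.44 ± 0.21. For red cell genes, 7 of 27 erythroid genes were higher and 20 did not pass, 21 passed adjusted over the list alone. The median was 1.25 (camera adjusted p = 2.38e-18, adjusted p = 0.142 with an estimated correlation); Rhag was at 3.08 ± 0.55 and Epb42 did not pass (2.28 ± 0.63, adjusted p = 0.056). FL LT-HSC c held the highest Alb (11.79), Afp (11.16) and Hbb-bh1 (9.03) of all arrays, and without FL LT-HSC c the median of the erythroid genes was 0.94. The hepatocyte and hepatoblast genes had a median of 0.30 (camera adjusted p = 0.0199, adjusted p = 0.525 with an estimated correlation), with none of 24 higher and 1 lower, and the call was lost without FL LT-HSC c (-0.01, adjusted p = 0.556) or FL MPP c (0.0631). Of lymphoid-priming genes 10 of 20 were lower and 10 did not pass, 1 higher and 12 lower adjusted over the list alone, with a median of -0.68 (camera adjusted p = 3.81e-14), and Flt3 at -1.98 ± 0.15. Of myeloid-priming genes 14 of 32 were lower and 18 did not pass, 2 higher and 19 lower adjusted over the list alone, with a median of -0.65 (camera adjusted p = 3.38e-13, adjusted p = 0.207 with an estimated correlation) and the macrophage colony-stimulating factor receptor Csf1r at -2.84 ± 0.29. Of 664 genes called, 306 were higher and 358 lower, but 678 and 539 of 1217 without the narrow arrays, 670 and 560 with the array spread as a covariate and 729 and 749 with array weights, so which direction has more calls depends on the setting. Without the sgEzh2 arrays, which leaves 1 FL MPP array, 120 were called. Without FL MPP a, b or c the counts were 393, 417 and 396.

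In BM, platelet genes were higher in LT-HSC than in MPP. Cavin2 was higher than in MPP by 3.89 ± 0.26, Pf4 by 2.93 ± 0.16, Mmrn1 by 2.87 ± 0.21 and Vwf, the von Willebrand factor gene, by 2.25 ± 0.20; 16 of 27 members were higher and 11 did not pass, 20 higher and 1 lower adjusted over the list alone, with a median of 1.01 (camera adjusted p = 6.7e-27). Dntt (-5.03 ± 0.36), Tespa1, a gene of T cell receptor signalling (-3.57 ± 0.18), Flt3 (-2.91 ± 0.15), the chromatin organizer Satb1 (-2.67 ± 0.16) and Cd34 (-1.71 ± 0.13) were lower. Of the lymphoid group 8 of 20 were lower and 12 did not pass, 1 higher and 10 lower adjusted over the list alone, with a median of -0.50 (camera adjusted p = 8.35e-09). Of the stem cell genes, 17 of 38 LT-HSC-associated genes were higher and 21 did not pass, 20 passed adjusted over the list alone. The median was 0.51 (camera adjusted p = 2.99e-17, adjusted p = 0.111 with an estimated correlation), with Slamf1 at 2.41 ± 0.18 and Clu at 1.87 ± 0.20. For macrophage markers, 7 of 22 macrophage genes were higher and 15 did not pass, 12 passed adjusted over the list alone. The median was 0.61 (camera adjusted p = 1.45e-10, adjusted p = 0.149 with an estimated correlation), with C1qa at 2.12 ± 0.26, and for stromal markers, 4 of 21 stromal and stellate cell genes were higher, 1 was lower and 16 did not pass, 11 and 2 passed adjusted over the list alone. The median was 0.43 (camera adjusted p = 7.44e-06, adjusted p = 0.149 with an estimated correlation), with Sparc at 2.62 ± 0.45. Without the 4 narrow arrays, among them BM LT-HSC c with the highest late neutrophil mean, the medians were 0.27 for macrophage genes and 0.29 for stromal and stellate cell genes. In the endothelial list, 7 of 19 endothelial genes were higher, 1 was lower and 11 did not pass, 7 and 1 passed adjusted over the list alone. The median was 0.28 (camera adjusted p = 6.69e-06, adjusted p = 0.0786 with an estimated correlation), with Kdr at 2.64 ± 0.21 and Cdh5 at 2.01 ± 0.21. For replication genes, 9 of 47 S phase genes were lower and 38 did not pass, 19 passed adjusted over the list alone. The median was -0.33 (camera adjusted p = 8.51e-12, adjusted p = 0.149 with an estimated correlation). Myeloid-priming genes split into 4 higher and 6 lower of 32, 8 and 10 adjusted over the list alone, with a median of -0.21 and a mean of 0.03 (camera adjusted p = 0.625, downward), and 3 were higher and 13 lower without the narrow arrays. Of 892 genes called, 434 were higher and 458 lower, but 838 and 618 of 1456 without the narrow arrays, 221 and 127 of those at least 2-fold and 416 and 571 after median centring, so here too the direction with more calls depends on the setting. Array weights gave 1721, a fit of these 2 groups alone 255 and leaving out the sgEzh2 arrays 486. Without BM MPP a, b or c the counts were 544, 418 and 489. Between FL and BM, 138 higher and 150 lower genes were shared, against 6.81 and 8.41 for independent lists, and 4 moved oppositely.

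LT-HSC and ST-HSC, both low in Cd48, were compared next. In FL, Slamf1 (1.82 ± 0.18), the mucin Muc13 (1.55 ± 0.20), and the platelet genes Treml1 (0.99 ± 0.13) and Itga2b (0.99 ± 0.14) were higher in LT-HSC, and 6 of 27 megakaryocyte and platelet genes were higher and 21 did not pass, 15 passed adjusted over the list alone. The median was 0.49 (camera adjusted p = 9.59e-18). Ccr9 (-3.40 ± 0.37), Cdh17 (-3.13 ± 0.19), Tlr7 (-3.04 ± 0.35), the secreted glycoprotein Stc1 (-2.66 ± 0.21) and Flt3 (-1.98 ± 0.15) were lower, and 7 of 20 lymphoid-priming genes were lower and 13 did not pass, 1 higher and 10 lower adjusted over the list alone, with a median of -0.45 (camera adjusted p = 4.21e-14). The leukocyte protein gene Plac8 (-1.26 ± 0.18) and the neutrophil elastase gene Elane (-2.10 ± 0.32) were lower too. In the interferon list, 4 of 42 interferon response genes were lower and 38 did not pass, 16 passed adjusted over the list alone. The median was -0.33 (camera adjusted p = 9.59e-18), with Ifi27 at -0.94 ± 0.12 and Rtp4 at -0.82 ± 0.13. Of 109 genes called, 18 were higher and 91 lower, against 1708 at an unadjusted p under 0.05, and 211 were called without the narrow arrays, 205 with the array spread as a covariate, 180 with array weights and 27 without the sgEzh2 arrays. Single arrays left out gave 63, 68 and 66 (FL ST-HSC a, b and c) and 58 (FL LT-HSC b).

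In BM, the same contrast again had platelet genes among those higher in LT-HSC: 13 of 27 megakaryocyte and platelet genes were higher, 1 was lower and 13 did not pass, 18 and 2 passed adjusted over the list alone. The median was 0.72 (camera adjusted p = 9.61e-21), with Cavin2 at 3.26 ± 0.26, Pf4 at 2.14 ± 0.16 and Vwf at 2.04 ± 0.20. Clu (2.05 ± 0.20), Kdr (2.10 ± 0.21) and C1qa (2.11 ± 0.26) were also higher. Flt3 (-2.59 ± 0.15), Tespa1 (-2.48 ± 0.18), the chemokine Ccl3 (-2.45 ± 0.17), Dntt (-2.22 ± 0.36), Satb1 (-1.55 ± 0.16) and Cd34 (-1.40 ± 0.13) were lower. For mitosis, 17 of 53 G2M phase genes were higher and 36 did not pass, 37 passed adjusted over the list alone. The median was 0.64 (camera adjusted p = 1.73e-31, adjusted p = 0.161 with an estimated correlation), but BM ST-HSC b and c and BM LT-HSC c are narrow, and without the 4 narrow arrays, which leaves 1 BM ST-HSC array, the median was 0.21 and Cdk1, at 1.23 ± 0.22 here, was not called (0.57, adjusted p = 0.343). For B cell markers, 4 of 17 B cell genes were higher and 13 did not pass, 10 passed adjusted over the list alone. The median was 0.77 (camera adjusted p = 6.2e-10, adjusted p = 0.227 with an estimated correlation). The spread within BM LT-HSC was wide, with Jchain from 8.32 to 10.89. BM LT-HSC c had a late neutrophil marker mean of 10.63, against 8.45 to 9.05 in the other BM arrays, and Cd48 at 11.40. Without BM LT-HSC c the median of the B cell genes was 0.45, and without the 4 narrow arrays 1 of them was higher. In the immediate early group, 5 of 30 immediate early genes were lower and 25 did not pass, 11 passed adjusted over the list alone. The median was -0.42 (camera adjusted p = 5.53e-09, adjusted p = 0.161 with an estimated correlation), with Nr4a1 at -2.26 ± 0.37 (-1.53 and adjusted p = 0.113 without the narrow arrays). Of 334 genes called, 236 were higher and 98 lower, against 170 and 137 after median centring, 275 and 200 after repeated quantile normalization, 11 calls in a fit of these 2 groups alone, 821 with the array spread as a covariate, 4940 with array weights and 118 without the sgEzh2 arrays. Single arrays left out gave 685 (BM ST-HSC a), 152 (BM ST-HSC b), 101 (BM ST-HSC c) and 812 (BM LT-HSC c). FL and BM shared 7 higher and 17 lower genes, against 0.218 and 0.457 for independent lists, and 6 moved oppositely; over all genes the differences of the sources correlated at -0.07.

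ST-HSC were last compared with MPP. In FL, Pdzk1ip1 (3.65 ± 0.28), Fn1 (2.70 ± 0.33), Itsn1 (2.69 ± 0.31), Igf2 (2.33 ± 0.16), Mecom (2.27 ± 0.26) and Mllt3, a cofactor of transcription elongation (1.89 ± 0.20), were higher in ST-HSC, and Cd48 (-2.39 ± 0.30), Csf1r (-1.58 ± 0.29) and the growth regulator Myc (-1.23 ± 0.19) lower. Of the stem cell genes 15 of 38 were higher and 23 did not pass, 22 higher and 2 lower adjusted over the list alone, with a median of 0.59 (camera adjusted p = 3.71e-22, adjusted p = 0.0534 with an estimated correlation). For imprinted genes, 6 of 21 imprinted genes were higher and 15 did not pass, 9 passed adjusted over the list alone. The median was 0.47 (camera adjusted p = 8.94e-11), with Igf2r at 2.73 ± 0.43. For interferon, 10 of 42 interferon response genes were higher and 32 did not pass, 17 passed adjusted over the list alone. The median was 0.39 (camera adjusted p = 1.72e-12). Of the homeobox group, 4 of 24 Hox genes and cofactors were higher and 20 did not pass, 8 passed adjusted over the list alone. The median was 0.24 (camera adjusted p = 2.17e-06, adjusted p = 0.0674 with an estimated correlation), with the cofactor Meis2 at 1.16 ± 0.22. In the endothelial list 6 of 19 were higher and 13 did not pass, 8 higher and 1 lower adjusted over the list alone, with a median of 0.45 (camera adjusted p = 1.09e-09), Cdh5 at 2.44 ± 0.21 and Robo4 at 1.56 ± 0.29. Of 441 genes called, 309 were higher and 132 lower, and 1268 were called without the narrow arrays, 994 with the array spread as a covariate, 1751 with array weights, 963 in a fit of these 2 groups alone and 33 without the sgEzh2 arrays, with 1 FL MPP array left. Counts without FL MPP a, b, c and FL ST-HSC c were 279, 253, 215 and 255.

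In BM, cell cycle genes were lower in ST-HSC than in MPP: 32 of 47 S phase genes were lower and 15 did not pass, 42 passed adjusted over the list alone. The median was -0.64 (camera adjusted p = 5.49e-25, adjusted p = 0.0829 with an estimated correlation), and 36 of 53 G2M phase genes were lower and 17 did not pass, 47 passed adjusted over the list alone. The median was -0.83 (camera adjusted p = 9.99e-29, adjusted p = 0.124 with an estimated correlation). Bub1b was at -1.68 ± 0.29, Ttk at -1.57 ± 0.28, Cdk1 at -1.40 ± 0.22 and the replication gene Gins1 at -1.36 ± 0.21. Without the 4 narrow arrays, which leaves 1 BM ST-HSC array, Bub1b (-0.67), Ttk (-0.71), Cdk1 (-0.82) and Gins1 (-0.96) were smaller and not called (adjusted p = 0.124, 0.226, 0.0585 and 0.0866), the joint median of both lists was -0.43 against -0.73, and 5 S phase and 2 G2M phase genes were lower and 1 S phase gene higher. Jchain (-3.59 ± 0.44), Dntt (-2.81 ± 0.36), the mast cell protease Cpa3 (-2.71 ± 0.39), Ly86 (-2.49 ± 0.40), Cd48 (-2.43 ± 0.30) and Il7r (-1.95 ± 0.29) were lower, and Mmrn1 (1.76 ± 0.21), Mllt3 (1.37 ± 0.20) and the imprinted gene Ndn (1.31 ± 0.20) higher. For stem cell genes, 9 of 38 LT-HSC-associated genes were higher and 29 did not pass, 19 passed adjusted over the list alone. The median was 0.42 (camera adjusted p = 4.5e-11, adjusted p = 0.227 with an estimated correlation). In the lymphoid list, 7 of 20 lymphoid-priming genes were lower and 13 did not pass, 8 passed adjusted over the list alone. The median was -0.36 (camera adjusted p = 7.45e-06, adjusted p = 0.0829 with an estimated correlation), and in the myeloid list, 14 of 32 myeloid-priming genes were lower and 18 did not pass, 15 passed adjusted over the list alone. The median was -0.44 (camera adjusted p = 7.4e-06, adjusted p = 0.356 with an estimated correlation), with Ctsg at -2.38 ± 0.41. Of 1190 genes called, 255 were higher and 935 lower (21.4% higher), 368 and 658 (35.9%) after repeated quantile normalization, and 483 were called without the narrow arrays, 53.2% of them higher, 7647 with array weights and 559 without the sgEzh2 arrays. Counts without 1 array were 3444, 443 and 350 (BM ST-HSC a, b and c) and 581, 344 and 696 (BM MPP a, b and c). FL and BM shared 54 higher and 66 lower genes, against 4.04 and 6.33 for independent lists, and 3 moved oppositely.

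Whether the difference of LT-HSC from MPP itself differed between FL and BM was tested with an interaction contrast. Dntt was lower in LT-HSC than in MPP of BM, where MPP reached 11.63 ± 0.21, and near the bottom of the scale in FL MPP (5.22 ± 0.24, n = 3), and the differences of the 2 sources differed by 5.0 ± 0.51 (adjusted p = 0.000146). Pdzk1ip1 (2.34 ± 0.40), Igf2 (1.62 ± 0.23), Selp (1.66 ± 0.22) and Satb1 (1.33 ± 0.22) also had a higher LT-HSC minus MPP difference in FL than in BM. Cdh17 (-3.59 ± 0.28), Cybb (-3.50 ± 0.51), Cavin2 (-3.15 ± 0.37), Csf1r (-2.59 ± 0.41), Ebf1 (-2.14 ± 0.29) and Mmrn1 (-2.08 ± 0.30) had a lower one. Among platelet genes 1 rose and 4 fell of 27, 1 and 11 adjusted over the list alone, with a median of -0.41 (camera adjusted p = 9.28e-08). For the myeloid list 4 of 32 fell and 28 did not pass, 1 higher and 17 lower adjusted over the list alone, with a median of -0.96 (camera adjusted p = 9.32e-13, adjusted p = 0.368 with an estimated correlation), and for macrophage markers 1 of 22 macrophage genes was lower and 21 did not pass, 4 passed adjusted over the list alone. The median was -0.58 (camera adjusted p = 2.3e-08, adjusted p = 0.368 with an estimated correlation). Without BM LT-HSC c, the array with the highest granule gene mean, the medians shrank to -0.50 for myeloid-priming genes and -0.24 for macrophage genes, while 231 genes were called. Without the 4 narrow arrays 8 platelet genes fell. In all 106 genes were called, 42 higher and 64 lower, against 66, 68 and 64 without FL MPP a, b or c and 61 and 62 without BM MPP b or c. Without the sgEzh2 arrays, which leaves FL MPP c alone in its group, 3 were called, all lower, and a fit of these 4 groups alone called 54. Calls rose to 306 without the narrow arrays, 334 with array weights and 270 with the array spread as a covariate. The F test of the whole interaction of source and population called 160 genes, and single arrays left out gave 95, 99 and 83 (FL MPP a, b and c), 474 and 105 (BM ST-HSC a and c), 94 and 92 (BM MPP b and c) and 583 (BM LT-HSC c). It called 10 without the sgEzh2 arrays, 58 without FL ST-HSC b and c, 313 without the narrow arrays, 374 with the array spread as a covariate and 3555 with array weights.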

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

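Of the tests in this part, the narrow arrays for the granule genes, the covariation of hepatocyte genes, FL LT-HSC c alone for Alb and the narrow spread for cell cycle genes were chosen after the result was seen. The difference of LT-HSC from MPP was itself different between FL and BM for 106 genes by the interaction contrast, and the F test over source and population called 160. Of genes named for this, the LT-HSC minus MPP difference was higher in FL for Dntt (5.0), Pdzk1ip1 (2.34), Chdh (2.17), Ccl4 (1.97), Slc4a8 (1.94), Selp (1.66), Igf2 (1.62), Klrb1c (1.35), Satb1 (1.33), Cd34 (1.12) and Pecam1 (0.95). It was lower in FL for Cdh17 (-3.59), Cybb (-3.50), Cavin2 (-3.15), Clec5a (-3.03), Ccr9 (-2.89), Pirb (-2.85), Siglech (-2.79), Fcgr3 (-2.73), Csf1r (-2.59), Ebf1 (-2.14), Mmrn1 (-2.08), Il7r (-1.99), C1qa (-1.82) and Ccr3 (-1.40). Calls of 8 of these were lost when 1 array was left out: Il7r without any of FL MPP a, b and c, FL LT-HSC a and b and BM MPP a, b and c (adjusted p = 0.0586 to 0.0952), Chdh without FL LT-HSC a (0.0635), FL MPP b (0.0657) or BM MPP b (0.0674), Fcgr3 without FL MPP a (0.0566), FL MPP c (0.0613) or BM MPP c (0.0585), Klrb1c without FL MPP b (0.0511) or BM MPP b (0.0514), Pecam1 without FL MPP a (0.0723), FL LT-HSC c (0.0652), BM MPP a (0.0537) or BM MPP b (0.0725), Ccr3 without FL MPP a, b or c, FL LT-HSC a, b or c or BM MPP b or c (0.0573 to 0.12), C1qa without FL MPP a, b or c, FL LT-HSC a or c or BM MPP b or c (0.0511 to 0.091), and Clec5a without FL MPP a or c, FL LT-HSC a or c or BM MPP a, b or c (0.0503 to 0.0755). The same contrast differed for the lists of platelet genes (median -0.41), myeloid-priming genes (-0.96), macrophage genes (-0.58) and stromal genes (-0.44), where camera with an estimated correlation gave adjusted p = 0.013, 0.368, 0.368 and 0.186. Outside the gene tests, 457 of 2631 probe sets with no single gene symbol passed between FL and BM in the average, 251 higher and 206 lower.

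Neutrophil granule genes were lower in FL than in BM, with a median of -4.84 over 8 genes. The 4 narrow arrays are excluded as the cause, since the median without them was -4.60. Mature neutrophil RNA carried into the BM arrays may contribute, although the sort of lineage-negative cells positive for Sca-1 and Kit should remove such cells: a median of -1 or lower was expected of 12 late neutrophil markers, and it was -1.22, with 10 lower. In MPP, however, those markers had a median of -0.20 (quartiles -1.66 and -0.11), with 4 of 12 lower. Their array means were 7.63 to 7.69 in FL MPP and 8.45 to 8.77 in BM MPP. The granule genes had a median of -4.12 in MPP, with 8 of 8 lower. They define the pattern, and Lcn2, Mmp8 and Chil3 were in no list fixed beforehand, so that count is no test. Carried-over RNA as the only source is therefore not settled in MPP. A difference of age or tissue in the sorted cells stays open, as untested.

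Of the hepatocyte list 7 of 24 genes were higher in FL, Alb most of all, 2 were lower and 15 did not pass, with a median of 0.18 (camera adjusted p = 0.0357, 0.545 with an estimated correlation). For Alb, FL LT-HSC c alone is excluded as the cause, since Alb without it still differed by 2.37, but for the list it was not tested: the median of the hepatocyte genes in the average without FL LT-HSC c was 0.12, and the call was lost there (adjusted p = 0.0697) as it was without each of 5 other arrays, 4 of them BM, so the loss shows a p near the bound. Hepatocyte RNA carried into FL arrays in varying amounts is a candidate explanation, although the gates for Sca-1 and Kit should leave hepatocytes out: over the FL arrays, centred on their groups, the other list members had a median correlation with Alb of 0.727, and 19 of 23 were positive, against a median of -0.05 for 10000 random lists matched on mean value. Expression of liver genes by the sorted cells was not tested.

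S and G2M phase genes were lower in BM ST-HSC than in BM MPP, with a joint median of -0.73 over 100 genes. Genes of like brightness fell less: 10000 random lists matched on mean value had a median of -0.14 and a lowest of -0.27, which put the joint median at percentile 0. The random lists were drawn gene by gene, while the S and G2M lists had estimated correlations of 0.30 and 0.47. The percentile therefore does not exclude compression of bright genes. The narrow spread of BM ST-HSC b and c may account for part: the median was -0.58 with the interquartile range as a covariate, past the bound set against this cause, but -0.43 without the narrow arrays, between the bounds. BM ST-HSC a gave -0.43, b -0.77 and c -0.95, and with 1 array left a lower rate of division of BM ST-HSC and the spread of the arrays cannot be told apart.

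Other splits of the arrays were counted for each comparison. For the average of FL and BM, 1 of 100 splits within populations called as many genes, a share under 0.05. It was the real one, with 4904 against 873 at most in the others. For the interaction, 100 shuffles of the residuals, the real order among them, took their place. For the contrast 1 called as many (106 against 2 at most in the others), a share under 0.05. For the F test 2 did, also a share under 0.05, though the other called 244 genes, more than the real 160. These splits and shuffles treat the arrays as exchangeable and independent, which the labels do not state. They therefore do not exclude chance at the level of animals. The 10 splits of 3 arrays against 3 are too few for a share under 0.05. Real and highest other counts were 1495 and 2 for FL against BM in LT-HSC, 3638 and 0 in ST-HSC and 1067 and 0 in MPP, with 1 split each at the real count. They were 664 and 1 for LT-HSC against MPP, 109 and 3 for LT-HSC against ST-HSC and 441 and 0 for ST-HSC against MPP in FL, and 892 and 0 for LT-HSC against MPP and 1190 and 0 for ST-HSC against MPP in BM. For LT-HSC against ST-HSC in BM 2 splits called as many as the real one: 334 against 5880 for the split of BM LT-HSC a and b and BM ST-HSC a from the 3 narrow BM arrays, which points to a structure of the samples.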

How the results depend on the processing

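Leaving out the 4 narrow arrays and the covariates for array spread and hepatocyte genes were chosen after seeing the data. Counts of called genes are given in the order FL against BM on average, in LT-HSC, in ST-HSC and in MPP, then in FL LT-HSC against MPP, LT-HSC against ST-HSC and ST-HSC against MPP, then the same in BM, with the interaction contrast and F test last. With 1 array left out they ran from 4141 to 5943, 947 to 1655, 1462 to 6125, 635 to 725, 393 to 547, 58 to 92, 215 to 375, 418 to 1105, 101 to 812, 344 to 3444, 61 to 231 and 83 to 583, and list calls from 188 to 207. At 2-fold or more, fewer by construction, they were 443, 568, 690, 416, 307, 54, 203, 348, 158 and 254. Without the arrays described as sgEzh2, which leaves 1 FL MPP array, they were 2538, 684, 1462, 261, 120, 27, 33, 486, 118, 559, 3 and 10. A lone array is assumed to vary like the others. For the settings that follow, only counts moved by more than 1.5 times are given and the cause was not tested. Without the narrow arrays, which leaves 1 BM ST-HSC array: FL against BM in ST-HSC 1207 and in MPP 2136; in FL 1217, 211 and 1268; in BM LT-HSC against MPP 1456 and ST-HSC against MPP 483; interaction 306 and 313. With array spread as a covariate: FL against BM in LT-HSC 2645, ST-HSC 1755 and MPP 2029, in FL 1230, 205 and 994, LT-HSC against ST-HSC in BM 821, interaction 270 and 374. With array weights: FL against BM in ST-HSC 8827 and MPP 3606, in FL 1478, 180 and 1751, in BM 1721, 4940 and 7647, interaction 334 and 3555. In fits of only the groups compared: FL against BM in LT-HSC 372 and MPP 2760, ST-HSC against MPP in FL 963, LT-HSC against MPP in BM 255, LT-HSC against ST-HSC in BM 11, interaction 54. Without FL ST-HSC b and c, 1 array left: FL against BM in ST-HSC 684, LT-HSC against ST-HSC in FL 20, ST-HSC against MPP in FL 83, F test 58. With the hepatocyte covariate: FL against BM on average 2786 and in LT-HSC 854. List calls fell from 206 to 39 with an estimated correlation. A fixed replicate block changed no count by more than 1.5 times. It gave 4858 for the average, 1460, 3622 and 1042 in the populations and 605, 94 and 385 in FL. In BM it gave 835, 244 and 1129, and for the interaction 80 and 120. For FL against BM it joined embryo and adult arrays of 1 letter, so it cannot account for animals shared within a source. In the average, a random block of source and letter gave 4590 calls, and the mean over populations per source and letter 4013. Of 18 correlations between arrays of 1 letter within a source, 4 passed 0.1, all in BM, with a range from -0.46 to 0.42. With 3 arrays per group this cannot show whether arrays of 1 letter pair. Of 376 gene results named, 367 were called and 229 of these were unchanged under all settings run; calls were lost for 98 without the sgEzh2 arrays, 44 of 288 in fits of only the groups compared, 39 without FL ST-HSC b and c and 26 without the narrow arrays, and none changed sign. Of 206 list calls 39 were unchanged under all settings, and calls were lost for 33 without the narrow arrays, where 2 more turned and were not called, 30 without the dimmest genes, 27 with array spread as a covariate, 22 without the sgEzh2 arrays and 21 after repeated quantile normalization. Lists whose test changed direction with 1 array left out, none called there, had medians in the interaction from -0.059 to 0.437 for hepatocyte genes, 0.00062 to 0.384 for LT-HSC-associated genes and -0.39 to 0.012 for mast cell, basophil and eosinophil genes. In FL they ran from -0.0069 to 0.462 for hepatocyte genes in LT-HSC against MPP, and in LT-HSC against ST-HSC from -0.038 to 0.444 for hepatocyte and 0.019 to 0.910 for erythroid genes. In BM they ran from -0.282 to 0.0015 for Polycomb genes in LT-HSC against MPP and -0.010 to 0.272 for T and NK cell genes in LT-HSC against ST-HSC. The arrays behind the changes were FL LT-HSC c for hepatocyte and erythroid and BM LT-HSC c for the other lists. Without the narrow arrays the Polycomb median was 0.0015 and that of LT-HSC-associated genes in the interaction -0.056, and without members shared between lists adhesion genes for LT-HSC against MPP in FL were at 0.086. Signal near background limits dim genes: differences of genes near the bottom of the scale, such as Uty in BM at 3.92, are compressed.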

Other observations

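Metabolic and growth groups also differed between FL and BM in the average over populations. For respiration, 23 of 52 oxidative phosphorylation genes were higher and 29 did not pass, 25 passed adjusted over the list alone. The median was 0.18 (camera adjusted p = 2.13e-07, adjusted p = 0.281 with an estimated correlation), with Ndufs1 of complex I at 0.54 ± 0.12 and the ATP synthase gene Atp5c1 at 0.52 ± 0.09; without the narrow arrays 12 were higher. For ribosomes, 24 of 38 ribosome biogenesis genes were higher, 1 was lower and 13 did not pass, 26 and 1 passed adjusted over the list alone. The median was 0.33 (camera adjusted p = 3.71e-09, adjusted p = 0.148 with an estimated correlation), with Mrto4 at 0.98 ± 0.15 and Utp20 at 0.72 ± 0.17, while Myc was lower (-0.58 ± 0.11). In sugar metabolism, 10 of 20 glycolysis genes were higher, 3 were lower and 7 did not pass, 12 and 4 passed adjusted over the list alone. The median was 0.31 (camera adjusted p = 0.0315, adjusted p = 0.312 with an estimated correlation), with the glucose transporter Slc2a1 at 0.89 ± 0.16; the list call was lost without FL ST-HSC b (adjusted p = 0.0623) or FL LT-HSC c (0.052). In sterol synthesis, 10 of 20 cholesterol synthesis genes were higher, 1 was lower and 9 did not pass, 10 and 1 passed adjusted over the list alone. The median was 0.22 (camera adjusted p = 0.0357, adjusted p = 0.525 with an estimated correlation), lost without FL LT-HSC a (0.0558), FL ST-HSC b (0.0632), BM ST-HSC b (0.0545), BM ST-HSC c (0.0571) or BM LT-HSC c (0.116). The calls of these 2 lists were also lost without the narrow arrays and after repeated quantile normalization. For genome repair, 14 of 28 DNA repair and Fanconi genes were higher and 14 did not pass, 18 passed adjusted over the list alone. The median was 0.25 (camera adjusted p = 1.79e-05, adjusted p = 0.214 with an estimated correlation), and the Fanconi gene Fancb was at 1.0 ± 0.15.

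Stress and surface groups were mixed. For protein folding stress, 1 of 26 unfolded protein response genes was higher, 10 were lower and 15 did not pass, 3 and 12 passed adjusted over the list alone. The median was -0.15 (camera adjusted p = 0.00118, adjusted p = 0.165 with an estimated correlation), with the chaperone Dnajb9 at -0.93 ± 0.08. Among chromatin repressors, 3 of 26 Polycomb genes were higher, 4 were lower and 19 did not pass, 10 and 5 passed adjusted over the list alone. The median was 0.15 (camera adjusted p = 0.167), and Ezh1 was lower by -0.59 ± 0.09 while Ezh2 did not pass. Of homeobox genes, 6 of 24 Hox genes and cofactors were higher, 1 was lower and 17 did not pass, 6 and 1 passed adjusted over the list alone. The median was 0.05 (camera adjusted p = 0.217). In heme and iron metabolism, 1 of 20 heme synthesis and iron genes was higher, 4 were lower and 15 did not pass, 1 and 4 passed adjusted over the list alone. The median was -0.09 (camera adjusted p = 0.18), and for cytokine receptors, 6 of 37 cytokine receptor genes were higher, 9 were lower and 22 did not pass, 7 and 11 passed adjusted over the list alone. The median was -0.06 (camera adjusted p = 0.178). Adhesion genes had 8 higher and 10 lower of 34, 11 and 11 adjusted over the list alone, with the cell adhesion molecule Alcam at -2.24 ± 0.09 and the integrin Itga9 at 1.51 ± 0.10, a median of 0.05 and a test pointing down (camera adjusted p = 0.555).

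The hypotheses below were written before their tests. Lin28b blocks the maturation of let-7, so its higher level in FL may go with higher levels of let-7 targets. The 16 targets, of which Tgfbr1 and Igf1r were also in the cytokine receptor list, had a median difference of 0.51. Of the targets 12 were higher and 2, Gatm and Slc20a1, were lower. The median lay at percentile 100 of 10000 random lists matched on mean value (median 0.06, 95th percentile 0.20). These lists were drawn gene by gene, and the correlation between the targets was not estimated. The percentile therefore does not exclude a shared shift of correlated genes. Some of the targets, such as Dna2 and Cdc25a, act in the cell cycle, so the shift of cell cycle genes stays open as another source. Kdm5d and Uty, high in FL and near the bottom of the scale in BM, may reflect BM from females and FL from at least some males. Then 4 X-linked genes that escape inactivation would be lower in FL, but their median difference was 0.05 and none of the 4 passed. A positive median was written beforehand as going against the explanation, and 0.05 met that bound. The quartiles had either sign (-0.09 and 0.17), and a stricter bound on the lower quartile, not written beforehand, was not passed. By that stricter bound these genes do not decide the sex of the animals. Kdm5d and Uty themselves did not overlap between sources. Kdm5d ran from 6.64 to 8.09 in FL and 4.07 to 4.88 in BM, and Uty from 6.92 to 7.77 and 3.77 to 4.17. These values go with the explanation, while Eif2s3y did not pass. In every FL against BM comparison sex may therefore differ together with age and tissue.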
